A study of Dokdonia sp. Dokd-P16 with 120 samples.

How the data were processed

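The series holds 120 RNA sequencing libraries of the marine flavobacterium Dokdonia sp. Dokd-P16. Per the labels, they form 24 groups of 5 replicates lettered A to E, from cultures kept under iron-deplete or iron-replete conditions. Per the labels, cells were collected on filters, RNA was extracted with the RNeasy PowerWater kit, ribosomal RNA was depleted with Ribo-Zero, and directional libraries were made with the NEBNext Ultra II kit and sequenced as read pairs on a NovaSeq instrument. Nothing in the labels says that the letters stand for separate cultures, so p-values measure only the spread between these libraries, which may be technical.

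The deposited unit is the expected count of read pairs per feature, 1 value per feature and library, as the authors obtained it with RSEM 1.3.1 after trimming with Trimmomatic 0.36, per the submitters' processing notes. The mapper, the strand setting of the counting and any filter on mapping are not given in the sources used here, so reads of overlapping or antisense neighbours cannot be told apart. The deposited table of the whole series and the files of single libraries held the same expected counts, with a largest difference of 0. Of 3202 features, 3146 were coding sequences, 9 rRNAs, 43 tRNAs, 3 other non-coding RNAs and 1 transfer-messenger RNA (tmRNA), which frees stalled ribosomes. Of all coding-sequence values, 0.604% were not whole at a tolerance of 1e-09. The files do not pair identifiers with gene names or products, 27 coding sequences carry no protein identifier, and no reference annotation was used. The lists of genes by function that had been fixed (iron uptake, iron storage and others) could therefore not be matched and were not tested.

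Expected counts were rounded to whole numbers. The 9 rRNA and 43 tRNA features were left out of library sizes and tests, since their counts follow the depletion step. Total expected counts per library ranged from 3485170 to 25816819 with a median of 12095346.5. Without rRNA and tRNA they ranged from 1808191 to 16843103. Between 3100 and 3133 coding sequences had a count in each library. Values per group are TMM-normalised CPM, with the mean and SD of the 5 replicates. Precision is limited by the spread between replicates, a biological coefficient of variation of 0.247 over all groups.

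The test of each contrast was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), with robust dispersions, trimmed mean of M values (TMM) scaling and edgeR's expression filter by group, in 1 model of the 24 groups with 96 residual degrees of freedom. The filter left 3116 features, of which 3112 were coding sequences. Adjusted p-values are Benjamini-Hochberg values within a contrast, and a gene is called at an adjusted p under 0.05. Log2 fold changes carry a standard error (SE) worked back from the test. It is the absolute log2 fold change divided by the square root of the F statistic. Contrasts were deplete against replete cells in 4 pairs of groups, viral lysate against medium control at 5 times in each iron condition, the difference between those lysate effects (interaction), and last against first time in 4 series. These contrasts, the tests and the alternatives were fixed before the data were examined. The difference in the change over time between iron conditions was added afterwards.

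Iron lists were taken from the cultures with nothing added, as genes at least 2-fold different with an adjusted p under 0.05 in the same direction at both of their times. They were tested under lysate with camera (limma 3.58.1), at a preset correlation of 0.01 between genes and again with an estimated correlation. Adjustment ran over the 20 tests. Named genes followed a rule fixed beforehand. A gene had to be called in the same direction in both contrasts without addition and in the medium control at T0 (iron), at 2 or more times (lysate), at 1 or more times (interaction), or within 1 series (change over time, where the planned rule of both iron conditions left none). It also needed a mean of 20 CPM or more in the higher group. Because the files give no names, at most 2 identifiers in each direction by mean log2 fold change are printed. Other coding sequences are given by the running number that ends their identifier and were chosen after their values were seen. That neighbouring numbers are neighbours on the chromosome was not checked against a genome. Neighbouring numbers were tested as runs of 3 or more against 1000 shuffles of the numbers. Differences of the summed CPM of a run were tested by exact permutation of the libraries on a log2 scale, with a pseudocount of 1 CPM.

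Same-lettered libraries did not deviate together: the mean correlation of their deviations from the group means was -0.00435 over 1380 pairs, against 0.00291 over 5520 pairs with different letters. Every pair of letters correlated above 0.1 in 1 of 18 contrasts, the change over time in replete cells with AQUIL (0.334 to 0.745), where edgeR called 0 genes with and without the letter as a block, against 71 at an unadjusted p under 0.05 and 0 by DESeq2 and limma voom. Elsewhere the letter pairs no libraries, and fits with it as a block are alternatives. Within groups no library duplicated another, since the closest pair still differed with a chi-square of 2.79 per degree of freedom, and correlations within groups ranged from 0.916 to 0.994. Pairs from different groups were not compared in this way.

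Alternatives were size factors of DESeq2 1.42.0 in place of TMM, no expression filter, a mean of 50 counts, the letter as a block, the letter within each iron condition, rRNA and tRNA kept, only the groups of a contrast, the DESeq2 Wald test, limma voom with sample quality weights, and each library left out in turn. For the iron lists, lists by adjusted p alone and lists from the medium control at T0 were tried. Blocks of 8 consecutive library numbers, fits without 2 or 8 libraries, both together, and fits without tmRNA and other non-coding RNA were added after the data had been seen. On simulated counts of 3115 genes for lysate against control in deplete cells at T4, 90% of 100 genes changed 2-fold and 98% of 100 changed 4-fold were recovered, and 3.35% of calls were unchanged genes. In replete cells at T4 these were 89%, 100% and 4.65%. For the interaction at T4 with the change placed in deplete cells they were 65%, 97% and 7.82%. Simulated counts were drawn independently for each library. They lacked any structure by library number, so these shares need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.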

Results

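Transcript abundance was measured by RNA sequencing in Dokdonia sp. Dokd-P16, a marine bacterium of the Flavobacteriia, in 120 libraries from 24 groups of 5 replicates. The series asks how such bacteria respond to the iron that becomes available when viruses lyse other cells. Cultures were iron-deplete or iron-replete. In each iron condition, cells received viral lysate (L) or the medium Aquil (AQUIL), a defined artificial seawater, as a control, and were sampled at the times T0 to T4. Cultures with nothing added (NOADD) were sampled at Tm1 and Tend. The labels give no hours for these times. Total expected counts per library ranged from 3485170 to 25816819, with medians of 7228943.5 in the 60 deplete and 13179966.5 in the 60 replete libraries. Ribosomal RNA took 19.5 to 67.1% of all counts. The tmRNA, which rescues stalled ribosomes, took 3.09 to 23.7% of all counts. The files do not pair features with gene names, so genes are given by protein identifier or by running number.

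The libraries carry numbers from 1 to 120, and these numbers run almost in parallel with the iron condition. Numbers up to 62 held 59 replete and 3 deplete libraries, and numbers from 63 held 57 deplete libraries and 1 replete library. Deviations of libraries from their group means were correlated at 0.358 between adjacent numbers and at 0.0554 at a distance of 12 numbers. A run of 8 neighbouring coding sequences, 2733 to 2740, chosen after their values were seen, separated lysate from non-lysate libraries in both iron conditions, with 8 exceptions among the 45 deplete and 60 replete libraries assessed. At these 8 coding sequences together, replete_L_T3 B held 817 CPM, replete_L_T0 D 867 CPM and replete_L_T4 E 1098 CPM, in the range of libraries without lysate. Without lysate, replete_AQUIL_T4 C held 185 CPM, replete_NOADD_Tend D 245 CPM and replete_AQUIL_T2 A 223 CPM, in the range of libraries with lysate. In the iron-deplete group deplete_AQUIL_T2, replicate B held 197 CPM, and replete_L_T3 D held 4456 CPM. For these last libraries the iron-gene score, the mean log2 level of genes higher minus genes lower in deplete cells, was 0.85 in the deplete and 3.93 in the replete library. All 8 libraries form 4 pairs of adjacent numbers. They were kept under their labels.

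**Figure D1:**
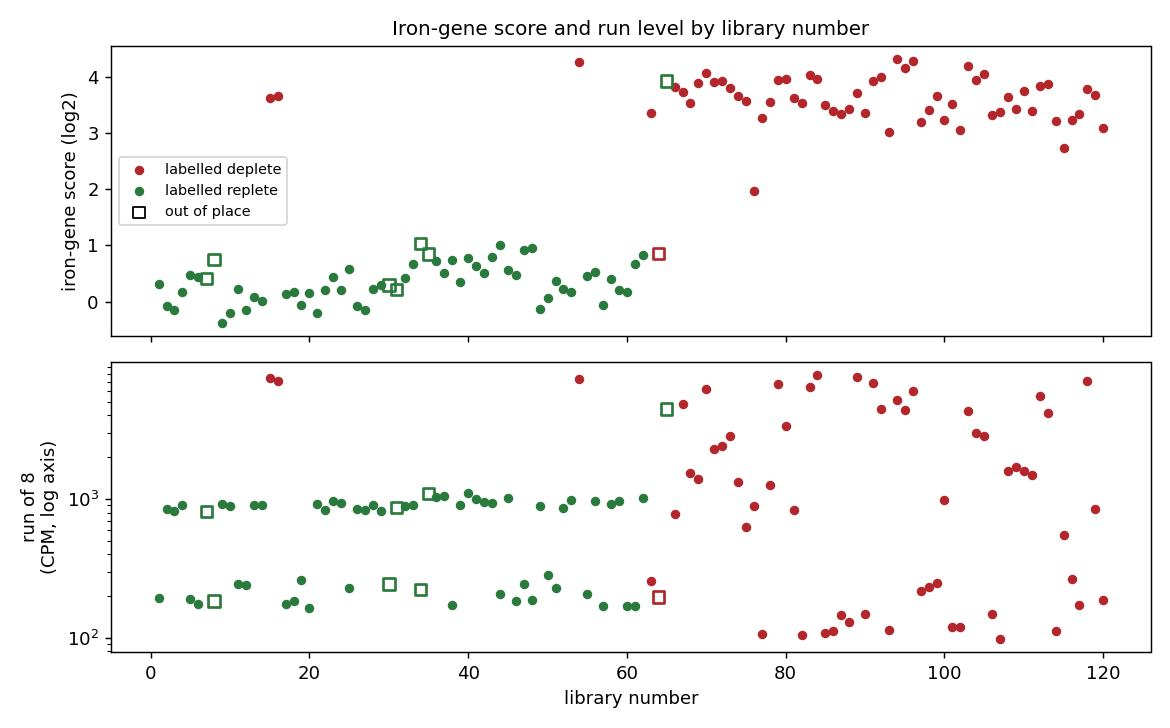
Iron-gene score (log2 units) and summed CPM of coding sequences 2733 to 2740 (log axis) of each of the 120 libraries against library number, with iron condition marked by colour and the libraries that stand apart by open squares. The 8 libraries that lie among another medium or iron condition stand in 4 pairs of adjacent numbers, such as deplete_AQUIL_T2 B at 197 CPM beside replete_L_T3 D at 4456 CPM.

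Which transcripts differ between deplete and replete cells was asked in NOADD at Tm1 and Tend and in AQUIL at T0 and T4. In all 4 contrasts, 264 genes were higher and 247 lower in deplete cells, and 17 of the former and 54 of the latter differed at least 2-fold in each. AWH74961.1 (coding sequence 2459) stood at 15162 ± 5208 CPM in deplete and 245 ± 83.5 CPM in replete cells of NOADD Tm1 (SD, n = 5), a log2 difference of 5.95 ± 0.70 (SE, edgeR adjusted p = 2.07e-10). It was higher by 4.56 ± 0.66 at Tend, 4.66 ± 0.66 in AQUIL T0 and 4.51 ± 0.65 in AQUIL T4. AWH74963.1, number 2461, was higher by 4.52 ± 0.53 at Tm1 (966 ± 224 against 42.1 ± 9.53 CPM) and by 2.97, 3.29 and 3.01 in the other contrasts. In the opposite direction, AWH75575.1 (number 3108) differed by -3.99 ± 0.91 in AQUIL T4 (2.58 ± 1.57 against 41.4 ± 25.4 CPM, edgeR adjusted p = 0.000152), while AWH75575.1 in iron effect AQUIL T4 stood at -2.59 (adjusted p = 0.0746) with blocks of 8 library numbers. AWH75578.1 (number 3111) differed by -4.07 ± 0.90 in NOADD Tend (3.85 ± 1.85 against 65 ± 81.2 CPM, edgeR adjusted p = 0.000133), and by -2.92 without replete_NOADD_Tend A.

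Several of the iron-dependent genes had adjacent numbers. Coding sequences 2458 to 2462 were higher in deplete cells with median log2 differences of 4.31 (NOADD Tm1), 2.87 (NOADD Tend), 3.29 (AQUIL T0) and 2.92 (AQUIL T4). For 2589 to 2592 the medians were 1.56, 1.82, 1.62 and 1.58, and for 881 to 883 they were 1.3, 1.04, 0.97 and 1.14. Coding sequences 1928 to 1931 had medians of 1.47, 1.01 and 1.08 in the first 3 contrasts and of 0.38 in AQUIL T4, where no member was called. Lower in deplete cells were 310 to 312, with medians of -2.07, -2.16, -2.18 and -2.44, and 2116 to 2119, with -1.67, -2.09, -1.72 and -2.27. Of 35 genes called higher in the first 3 contrasts with a mean of at least 2-fold, 16 lay in 4 such runs, against a mean of 0.015 in 1000 shuffles (permutation p = 0.000999, the smallest these shuffles can give, adjusted p = 0.002). Of 87 genes lower by the same limits, 7 lay in 2 runs, against a mean of 0.18 (permutation p = 0.002, adjusted p = 0.003).

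By contrast, edgeR called 928 genes in NOADD Tm1 (456 higher, 472 lower), 1318 in NOADD Tend (589 higher, 729 lower), 938 in AQUIL T0 (494 higher, 444 lower) and 1586 in AQUIL T4 (773 higher, 813 lower). Of 589 genes higher in NOADD Tend, 472 were also higher in AQUIL T4, where 146 would be expected of independent lists, and of 729 lower ones 576 were also lower (190 expected). These contrasts share no libraries. The iron list held 26 genes higher and 76 genes lower in deplete cells, chosen from both NOADD contrasts. In AQUIL, 25 of the 26 rose at T0 (median log2 difference 1.35) and 24 at T4 (median 1.59), while 65 of the 76 fell at T0 (median -1.38) and 74 at T4 (median -1.86). The tmRNA was lower in deplete cells by -1.46 ± 0.31 in NOADD Tm1, -1.23 ± 0.31 in AQUIL T0 and -0.98 ± 0.30 in AQUIL T4 (edgeR adjusted p = 0.000156, 0.00129 and 0.00511), and differed by 0.42 ± 0.30 in NOADD Tend (adjusted p = 0.264). In deplete NOADD Tend the tmRNA stood at 452101 and 475495 CPM in replicates C and D, which carry numbers 16 and 15 among the replete libraries, and at 89377 to 139820 CPM in the other 3. Library number and iron condition overlap almost fully: with blocks of 8 numbers, chosen after the data had been seen, the counts were 350 in NOADD Tm1, 1211 in NOADD Tend, 139 in AQUIL T0 and 1075 in AQUIL T4. These fits kept the 8 libraries named above. Without them as well, no iron count moved by over 1.5 times from the main fit. With limma voom the count for iron effect AQUIL T0 was 1844, and for iron effect NOADD Tend 2044.

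**Figure D2:**
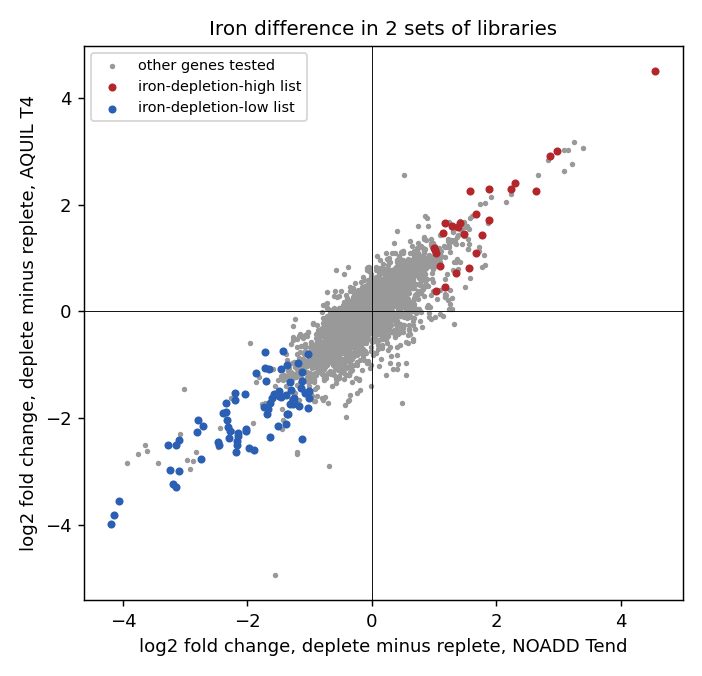
Log2 difference between deplete and replete cells of each gene in NOADD Tend (horizontal) and AQUIL T4 (vertical), with the 26 and 76 genes of the iron lists coloured. The lists were chosen on the horizontal axis; on the vertical axis 24 of the 26 rose and 74 of the 76 fell.

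**Figure D3:**
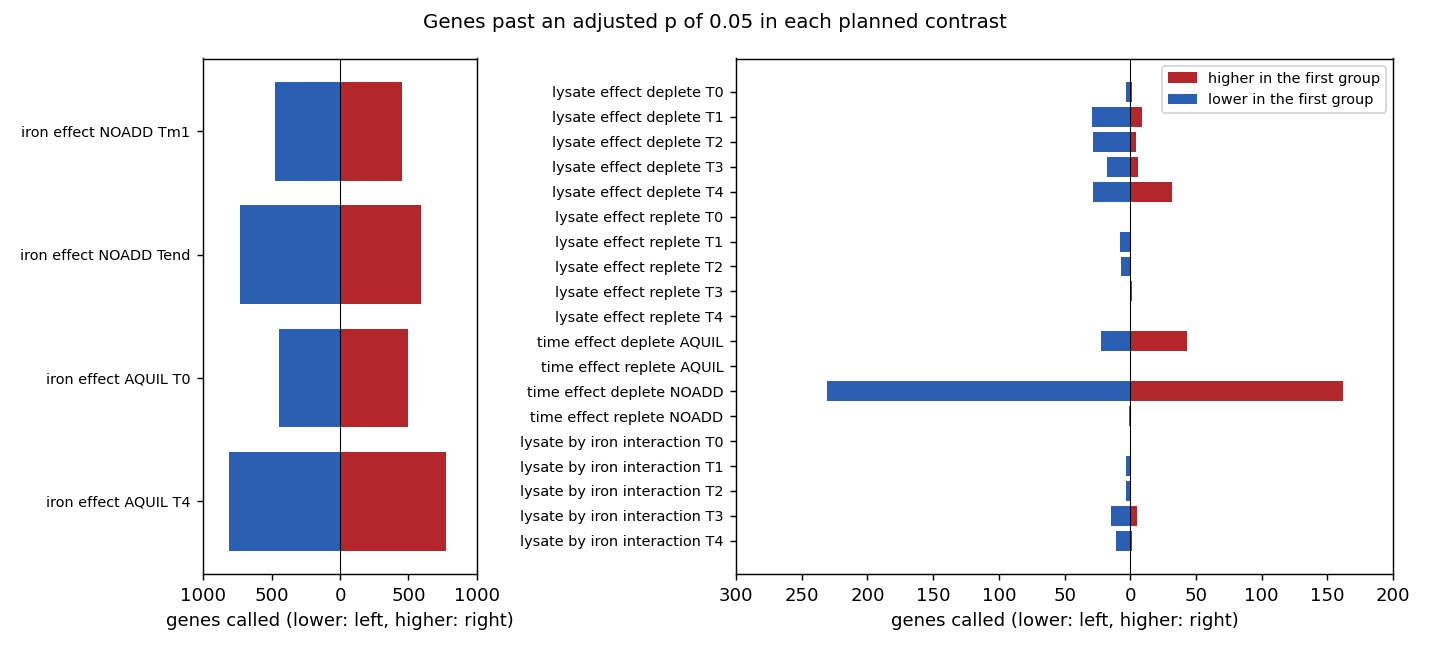
Number of genes called higher and lower by edgeR in each planned contrast, with the 4 iron contrasts on their own axis at the left. Counts run from 928 to 1586 for iron, from 4 to 60 for lysate in deplete cells and from 0 to 8 for lysate in replete cells.

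Whether the lysate changed transcript levels in iron-starved cells was asked by setting L against AQUIL at each time in the deplete condition. The 8 coding sequences 2733 to 2740 fell together from T1 on. Their summed level was 3041 ± 806 CPM in AQUIL and 244 ± 19.8 CPM in L at T1, 5816 ± 795 against 114.6 ± 9.19 CPM at T3, and 6218 ± 2083 against 135 ± 41.7 CPM at T4 (SD, n = 5). At T0 it was 1466 ± 330.2 in AQUIL and 729.6 ± 132 CPM in L. All 25 pairs of libraries were lower in L at each of the 5 times (exact permutation p = 0.00794 at each, two-sided, the smallest possible, adjusted p = 0.0132), with log2 differences of -0.99 at T0, -3.60, -3.98, -5.64 and -5.48. The run was chosen because its members were called lower with lysate in these same libraries. The p-values at T1 to T4 therefore restate that choice. By gene, edgeR called none of the 8 at T0 (median log2 difference -0.97) and all 8 at T1 to T4, with medians of -3.62, -4.51, -5.58 and -5.45. Without the 8 libraries named above 5 were called at T0, and with blocks of 8 numbers as well all 8 (median -1.17). AWH75224.1 (number 2737) fell by 5.93 ± 0.59 at T3 (7.40 ± 2.17 against 438 ± 65 CPM, edgeR adjusted p = 1.14e-13) and AWH75225.1 (number 2738) fell by 5.75 ± 0.57 at T4 (5.15 ± 3.06 against 286 ± 105.1 CPM, adjusted p = 8.15e-14).

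Other transcripts of deplete cells were also called between L and AQUIL. AWH73374.1 (number 798) rose by 1.75 ± 0.34 at T1 (663 ± 204 against 197 ± 20.3 CPM, edgeR adjusted p = 0.000355) and by 1.26 ± 0.34 at T3 (adjusted p = 0.0469), and was not called at T0, T2 or T4 (0.18, 0.23 and 0.37). AWH75537.1 (number 3066) rose by 1.25 ± 0.30 at T3 (71.6 ± 20.2 against 29.9 ± 7.75 CPM, edgeR adjusted p = 0.0119) and by 1.02 ± 0.30 at T4 (adjusted p = 0.0487), and was not called at T0, T1 or T2 (-0.22, 1.00 and 1.04). Its call at T3 ended without deplete_AQUIL_T3 D (1.14). The following were chosen after their values were seen. Coding sequence 1011 was at 132 ± 17.7 CPM in L and 1084 ± 218 CPM in AQUIL at T1, a difference of -3.03 ± 0.38 (edgeR adjusted p = 2.44e-09), and differed by -2.95, -3.63 and -3.38 at T2 to T4. Coding sequence 1007 fell at T1 to T4, with log2 differences of -1.93, -2.26, -2.38 and -1.5. Coding sequences 1566 to 1568 had medians of -0.52 at T1, -0.63 at T3 and -0.64 at T4, with 2, 3 and 3 members called. At T0, 4 genes were called: coding sequences 3059, 3060 and 3061 fell, with differences of -1.27, -1.73 and -2.04 (3061: 108.9 ± 44.4 against 450 ± 186 CPM, edgeR adjusted p = 0.000792), and 2589 rose by 1.92 ± 0.44 (2641 ± 781 against 696 ± 613 CPM, adjusted p = 0.0204).

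In all, edgeR called 38 genes at T1 (9 higher, 29 lower), 32 at T2 (4 higher, 28 lower), 24 at T3 (6 higher, 18 lower) and 60 at T4 (32 higher, 28 lower). Of the genes lower with lysate, 63 were called at 1 or more times, 21 at 2 or more and 10 at 4. Of those 21, 11 lay in 2 runs of adjacent numbers, 2733 to 2740 and 1566 to 1568 (permutation p = 0.000999, the smallest 1000 shuffles can give). Counts rested on single libraries: at T2 there were 49 without deplete_AQUIL_T2 B, and at T4 there were 24 without deplete_L_T4 B, 94 without deplete_L_T4 E and 121 without deplete_L_T4 D. Without the 8 libraries named above the counts at T0 to T4 were 11, 61, 60, 66 and 87. With blocks of 8 numbers they were 9 at T0, 34 at T1, 66 at T2, 128 at T4, and 51 higher and 63 lower at T3, and with limma voom 281 for lysate effect deplete T0, 280 for lysate effect deplete T1, 224 at T2, 293 for lysate effect deplete T3 and 124 at T4.

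**Figure D4:**
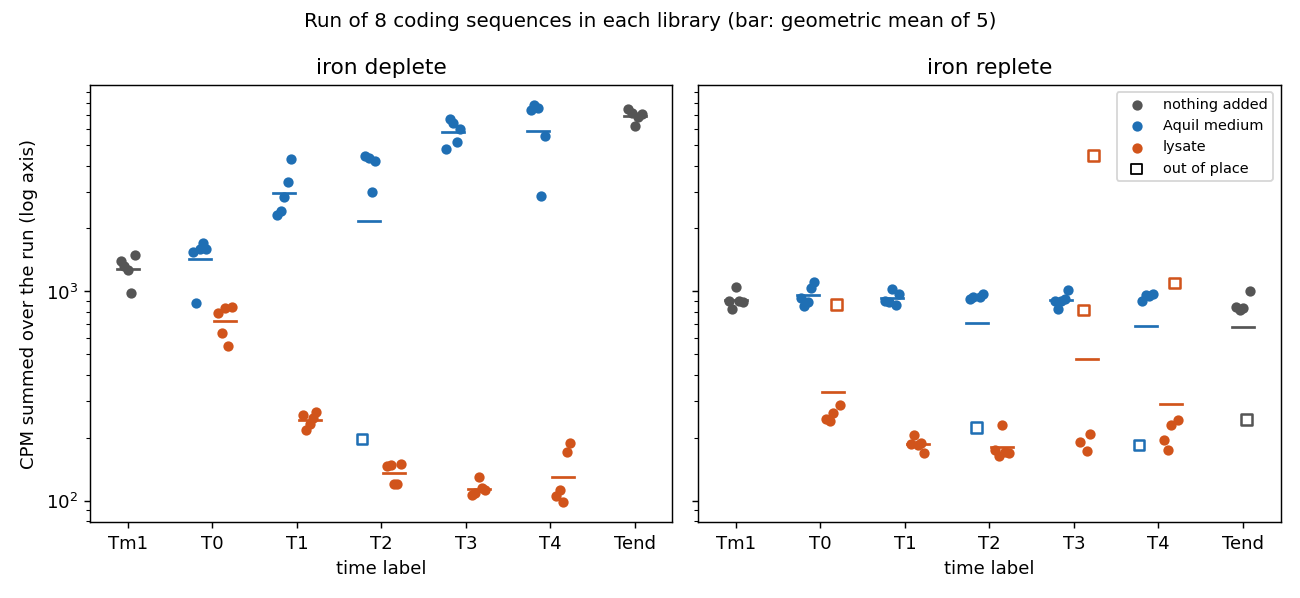
Summed CPM of coding sequences 2733 to 2740 (log axis) in each library by time, for deplete and replete cells, with bars at the geometric mean of 5 replicates and open squares for the 8 libraries that lie among another group. In deplete cells AQUIL stood at 3041 to 6218 CPM and L at 114.6 to 244 CPM from T1 to T4 (means).

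The same question in replete cells gave fewer calls. At T1 all 8 coding sequences 2733 to 2740 fell, with a median log2 difference of -2.23 and a summed level of 929 ± 66.8 CPM in AQUIL against 187 ± 13.2 CPM in L (SD, n = 5). AWH75225.1 fell by 2.65 ± 0.49 at T1 (6.56 ± 0.87 against 41.2 ± 7.16 CPM, edgeR adjusted p = 0.0015) and AWH75224.1 fell by 2.39 ± 0.49 (12.2 ± 1.98 against 64 ± 8.63 CPM, adjusted p = 0.00436). At T2, 7 of the 8 fell (median -2.16). At T0, T3 and T4 none was called, with medians of -1.43, 0.30 and -0.97. Without replete_L_T3 D the median at T3 was -1.32, and without replete_L_T4 E that at T4 was -1.85. With blocks of 8 numbers 6 of the 8 were called at T1 (median -2.38) and 4 at T2 (median -2.03), and the median at T3 was -0.33. On the summed level the exact permutation p was 0.00794 at T1 (the smallest possible), 0.0159 at T0, 0.0159 at T2, 0.357 at T3 and 0.198 at T4. Without the 8 libraries named above, which were chosen by this level, the medians at T0 to T4 were -1.99, -2.25, -2.41, -2.19 and -2.09, with all 8 called at each time. Coding sequence 1011 was not called in replete cells with all libraries, with differences of -1.47, -1.07, -1.23, 0.00 and -0.19 at T0 to T4. Without the 8 libraries it differed by -1.84, -1.10, -1.31, -1.13 and -0.98, with calls at T0, T1 and T2 (edgeR adjusted p = 2.63e-07, 0.00538 and 0.000394) and an adjusted p = 0.0523 at T3 and 0.128 at T4.

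The counts in replete cells at T0 to T4 were 0, 8, 7, 1 and 0 by edgeR, with all 15 calls of T1 and T2 lower with lysate and within the 8 neighbouring coding sequences. At an unadjusted p under 0.05 the counts at T0, T3 and T4 were 306, 93 and 44. DESeq2 called 0, 8, 8, 1 and 0, and limma voom 614 for lysate effect replete T0, 1301 for lysate effect replete T1, then 13, 19 and 16. The single call at T3 was coding sequence 2459, higher by 2.99 ± 0.61 (6074 ± 11460 against 763 ± 341 CPM, edgeR adjusted p = 0.0112), and it ended without replete_L_T3 D, or without replete_AQUIL_T3 C, D or E. Without the 8 libraries named above edgeR called 14, 10, 9, 8 and 9 genes. Leaving out replete_L_T0 D alone gave 8 calls at T0, leaving out replete_L_T1 C or E gave 5 at T1, and leaving out replete_L_T4 E gave 1 at T4. At T2 there were 0 calls without replete_L_T2 B, C or E, 1 without replete_L_T2 D, and 4 without replete_AQUIL_T2 B, C or D, with medians of the 8 coding sequences between -2.17 and -2.06.

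Whether iron status changed the lysate response was tested as the difference between the lysate effects of deplete and replete cells. The 8 coding sequences 2733 to 2740 fell further in deplete cells at T3 (median -5.53) and T4 (median -4.51), with all 8 called. At T0, T1 and T2 the medians were 0.45, -1.34 and -2.43 and none was called. Most of the difference at T3 and T4 lay in the control. Without the 8 libraries named above, mean summed levels in AQUIL were 5816 and 6218 CPM in deplete cells, against 912 and 946 CPM in replete cells. With lysate they were 114.6 and 135 CPM against 190 and 211 CPM. AWH75224.1 differed by -6.28 ± 0.73 at T3 (edgeR adjusted p = 2.25e-10) and AWH75226.1 (number 2739) by -6.34 ± 0.70 (adjusted p = 3.54e-11). Without replete_L_T3 D these became -4.47 and -4.52, both still called. In the other direction, AWH74560.1 (number 2043) differed by 4.32 ± 1.13 at T3 (edgeR adjusted p = 0.0406) and AWH74561.1 (number 2044) by 3.25 ± 0.74 (adjusted p = 0.0085). In deplete cells at T3 these stood at 620 ± 723 CPM in L against 69.8 ± 55.8 CPM in AQUIL, and at 129 ± 116.1 against 28.8 ± 10.7 CPM. Neither was called at another time, with differences of 0.09, 2.02, -1.63 and 1.33 for AWH74560.1 and 0.19, 2.02, -1.26 and 1.08 for AWH74561.1 at T0, T1, T2 and T4. The call of AWH74561.1 ended without deplete_L_T3 B (2.81) or E (2.88). That of AWH74560.1 ended without any of replete_AQUIL_T3 C, D or E, replete_L_T3 A, C or D, deplete_AQUIL_T3 A, B, D or E, or deplete_L_T3 B or E, with differences of 3.62 to 4.41. Without replete_L_T3 E they stood at 5.07 for AWH74560.1 and 4.17 for AWH74561.1. With blocks of 8 library numbers AWH74560.1 in lysate by iron interaction T3 stood at 3.17 (adjusted p = 0.0664) and the other at 2.23 (adjusted p = 0.114), so both calls ended, as they did without the 8 libraries named above (4.04 and 2.77, adjusted p = 0.346 and 0.16). At T1 the 3 calls were coding sequences 3063 (-2.26 ± 0.24), 3062 (-2.28 ± 0.37) and 597 (-0.73 ± 0.17). At T2 they were 2420 (-2.98 ± 0.64), 1007 (-2.32 ± 0.52) and 2419 (-3.04 ± 0.71), all chosen after their values were seen.

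The interaction counts of edgeR at T0 to T4 were 0, 3, 3, 20 and 12. At T0 the unadjusted count was 183, with 3 calls by DESeq2 and 540 by limma voom. At T3, 5 genes were higher and 15 lower, and at T4, 1 was higher and 11 lower. Without the 8 libraries named above the counts were 0, 10, 18, 10 and 10, and the medians of coding sequences 2733 to 2740 at T1 to T4 were -1.30 (5 called), -2.49, -3.28 and -3.32 (8 called at each). At T2 leaving out deplete_AQUIL_T2 B alone gave 19 calls, leaving out replete_L_T2 C gave 1, and leaving out replete_AQUIL_T2 E gave 2, and leaving out any other library except replete_L_T2 A (3) and deplete_L_T2 C (4) gave 0. At T3 there were 12 calls without replete_L_T3 D, deplete_L_T3 B or deplete_L_T3 E. At T4 there were 35 without deplete_L_T4 D, 22 without deplete_L_T4 E, 21 without deplete_L_T4 C and 19 without deplete_AQUIL_T4 A. At T0 there were 5 without deplete_L_T0 B, 3 without deplete_AQUIL_T0 B, 2 without replete_AQUIL_T0 A and 1 without replete_L_T0 E. With blocks of 8 numbers the counts at T0 to T4 were 6, 3, 7, 12 and 36, and by limma voom 540 for lysate by iron interaction T0, 1073 for lysate by iron interaction T1, then 51, 35 and 44.

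Whether lysate moved the iron-dependent genes was tested with the lists of 26 and 76 genes, which were chosen on the NOADD libraries. In deplete cells the 26 genes higher under iron depletion had median log2 lysate effects of -0.03, -0.51, 0.14, -0.24 and -0.08 at T0 to T4. Among them 1 rose at T0, 2 fell at T2, 1 fell at T3 and 1 fell at T4. The counts adjusted over the list alone were 2, 4, 8 and 4. The 76 genes lower under iron depletion had medians of 0.04, 0.04, -0.28, 0.19 and 0.21. Of these, 7 rose at T1 (7 adjusted over the list alone), 4 fell at T2 (9) and 1 rose at T3 (5). In replete cells the medians of the 26 genes were -0.02, 0.08, -0.04, 0.30 and -0.01, and those of the 76 genes 0.20, -0.19, 0.12, -0.35 and -0.14. At T3, 1 of the 26 rose (4 adjusted over the list alone) and 0 of the 76 fell by edgeR (3 adjusted over the list alone).

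No list passed once the correlation between genes was estimated, at 0.236 for the 26 genes and 0.259 for the 76. At the preset correlation, camera gave adjusted p-values of 0.000934, 0.00479, 0.172, 0.000358 and 0.00263 for the 26 genes in deplete cells at T0 to T4. With an estimated correlation the adjusted p = 0.631 at T2 and the adjusted p = 0.542 at the other times. For the 76 genes in deplete cells they were 0.0436, 0.0016, 0.000724, 0.000934 and 0.04, with an adjusted p = 0.631 at T0 and T4 and an adjusted p = 0.542 at T1 to T3 when the correlation was estimated. For the 26 genes in replete cells they were 0.914, 0.147, 0.914, 0.000119 and 0.277, with an adjusted p = 0.542 at T3 when the correlation was estimated. For the 76 genes in replete cells they were 0.000653, 0.000553, 0.021, 9.99e-20 and 3.41e-05. With an estimated correlation these became an adjusted p = 0.126 at T3, an adjusted p = 0.631 at T2 and an adjusted p = 0.542 at T0, T1 and T4. For the 26 genes the median and the direction of the test differed in deplete cells at T0 (median -0.03, mean 0.16, test upward) and T2 (median 0.14, mean -0.28, test downward). At T0 in replete cells the mean was 0.02 and the test pointed downward. Single libraries turned several medians. Without deplete_AQUIL_T2 B the 76 genes stood at 0.13 and the 26 genes at -0.02 in deplete cells at T2, and without replete_L_T3 D the 26 genes stood at -0.06 and the 76 genes at -0.10 in replete cells at T3. Without both of these libraries the preset adjusted p of the 76 genes in replete cells at T3 was 0.0106. In deplete cells at T0 the 26 genes stood at 0.14, 0.12, 0.01 and 0.12 without deplete_AQUIL_T0 A, B or D or deplete_L_T0 B, and the 76 genes at -0.01 without deplete_AQUIL_T0 E. At T1 the 76 genes stood at -0.02 without deplete_AQUIL_T1 B.

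The change over time was taken as T4 minus T0 in AQUIL and Tend minus Tm1 in NOADD. In deplete cells the 8 coding sequences 2733 to 2740 rose in both, by medians of 2.01 in AQUIL and 2.35 in NOADD, with all 8 called. AWH75224.1 rose by 2.18 ± 0.47 in AQUIL (469 ± 167 against 103.7 ± 21.2 CPM, edgeR adjusted p = 0.00196), and AWH75223.1 (number 2736) by 2.56 ± 0.43 in NOADD (275 ± 66.8 against 46.5 ± 4.81 CPM, adjusted p = 5.52e-05). AWH75226.1 rose by 2.16 ± 0.47 in AQUIL and by 2.47 ± 0.48 in NOADD. In AQUIL, AWH73373.1 (number 797) fell by 1.77 ± 0.36 (380 ± 68.7 against 1296 ± 1248 CPM, edgeR adjusted p = 0.0012) and AWH73374.1 fell by 1.72 ± 0.34. Both calls ended without deplete_AQUIL_T0 C, with differences of -0.97 and -1.0, and in fits of these groups alone (adjusted p = 0.0606 for AWH73373.1 in time effect deplete AQUIL and 0.0709 for AWH73374.1 in time effect deplete AQUIL). In NOADD, AWH72841.1 (number 245) fell by 1.59 ± 0.54 (edgeR adjusted p = 0.0422) and AWH74116.1 (number 1577) fell by 1.58 ± 0.49 (adjusted p = 0.0241). The call of AWH72841.1 ended without any 1 of the 10 libraries other than deplete_NOADD_Tm1 C, with differences of -1.66 to -1.44, and that of AWH74116.1 without deplete_NOADD_Tend A, C or D, with -1.50 to -1.42. The tmRNA rose by 1.47 ± 0.31 in NOADD (adjusted p = 0.000668), where replicates C and D of deplete Tend held 452101 and 475495 CPM, and the other 3, at 89377 to 139820 CPM, lay near the 74528 to 120739 CPM of Tm1. In replete cells the medians of the 8 coding sequences were -0.35 in AQUIL and -0.28 in NOADD, and none was called. No gene met the planned rule of a call in both iron conditions, so the genes named here were chosen within deplete cells after that was seen.

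EdgeR called 65 genes in deplete AQUIL (43 higher, 22 lower), 393 in deplete NOADD (162 higher, 231 lower), 0 in replete AQUIL and 1 in replete NOADD. In replete AQUIL the unadjusted count was 71, with 0 calls by DESeq2 and by limma voom. The call in replete NOADD was coding sequence 2046, chosen after its values were seen, which fell by 0.72 ± 0.16 (168 ± 17.5 against 275 ± 49.2 CPM, edgeR adjusted p = 0.0443). The count there was 0 without replete_NOADD_Tend A, B, C or E or replete_NOADD_Tm1 A, B or D, 3 without replete_NOADD_Tend D, and 6 without replete_NOADD_Tm1 C or E. DESeq2 gave 12 and limma voom 1077. In deplete AQUIL the count was 28 without deplete_AQUIL_T0 C, 38 without deplete_AQUIL_T4 C and 39 without deplete_AQUIL_T4 E. For time effect deplete NOADD it was 197, 226, 235 and 237 without deplete_NOADD_Tm1 B, deplete_NOADD_Tm1 C, deplete_NOADD_Tend A and deplete_NOADD_Tend E. With blocks of 8 numbers the deplete counts were 379 in AQUIL and 627 in NOADD.

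The difference between deplete and replete cells in this change over time was tested afterwards. In NOADD, 73 genes differed (46 higher, 27 lower), among them all 8 of coding sequences 2733 to 2740 (median 2.71) and the tmRNA (1.88 ± 0.43, edgeR adjusted p = 0.00755), with deplete_NOADD_Tend C and D again apart from the other 3. In AQUIL, 5 genes were called, and all were chosen after their values were seen. They were coding sequences 430 (1.01), 431 (0.81), 1566 (0.88), 1567 (0.84) and 1568 (0.86), with adjusted p-values of 0.0232 to 0.024 by edgeR, while 2733 to 2740 had a median of 2.35 with none called. Without the 8 libraries named above all 8 were called (median 2.09, largest adjusted p = 0.00118), with blocks of 8 numbers 5 (median 2.50), and with both all 8 (median 1.87). The AQUIL count was 0 without replete_AQUIL_T4 C or D, replete_AQUIL_T0 B or C, deplete_AQUIL_T0 C or deplete_AQUIL_T4 C, 1 without deplete_AQUIL_T4 E, and 2 without deplete_AQUIL_T0 B. It was 8 without replete_AQUIL_T4 A or deplete_AQUIL_T0 D, 9 without replete_AQUIL_T4 B, 10 without deplete_AQUIL_T0 A, 14 without deplete_AQUIL_T4 B and 22 without deplete_AQUIL_T4 A. The NOADD count was 34 and 36 without deplete_NOADD_Tm1 C and B, 73 higher and 40 lower without deplete_NOADD_Tm1 D, and 45 without deplete_NOADD_Tend A. It was 35 and 46 without replete_NOADD_Tm1 B and A, and 46 and 47 without replete_NOADD_Tend A and B. With blocks of 8 numbers the counts were 40 in AQUIL and 302 in NOADD.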

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

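In this part the tests on the libraries that stand apart, on the fall of coding sequences 2733 to 2740 and on library number in the iron contrasts were chosen only after the result was seen, as was the change over time compared between iron conditions. The depth test and the counts of splits were chosen before.

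In 96 tests of a group of 5 on 1 of 4 measures, 14 values lay far from the other 4 of their group, where chance gives about 1 in 20, or 4.8. Replicates deplete_AQUIL_T0 C and deplete_AQUIL_T2 B each account for 2 of them. On the log2 CPM of coding sequences 2733 to 2740 these were deplete_AQUIL_T0 C (9.79), deplete_AQUIL_T2 B (7.63), replete_AQUIL_T2 A (7.81), replete_AQUIL_T4 C (7.54), replete_L_T0 D (9.76), replete_L_T2 A (7.85), replete_L_T4 E (10.1) and replete_NOADD_Tend D (7.94). On the iron-gene score they were deplete_AQUIL_T0 C (1.97), deplete_AQUIL_T2 B (0.852), deplete_L_T0 B (2.74) and replete_L_T3 D (3.93). On the rRNA share of counts they were replete_L_T0 E (28.4%) and replete_NOADD_Tend C (23.8%).

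The first pattern is the 8 libraries whose level of coding sequences 2733 to 2740 lies among another medium or iron condition. If labels of neighbouring libraries exchanged places, each should have a neighbour by number that is out of place too, and 8 of 8 did, in 4 pairs of 1 lysate and 1 other label. In 100000 shuffles of the numbers, 1 gave as many (permutation p = 2e-05). Outside the run, 6 of the 6 replete libraries with a replete neighbour lay nearer the other medium at AWH75652.1, coding sequence 1011, against 0 of 53 libraries in place. Nearness was judged by local means over 8 numbers either side. This coding sequence was chosen after its values were seen, and it also fell with lysate in deplete cells. If reads of neighbouring libraries were mixed, intermediate levels would be seen, and the median share of the neighbour's condition was instead 1.00 (0.83 to 1.21). An exchange of neighbouring labels or tubes may therefore account for these libraries, but nothing in the labels bears on where it could have happened, and no biological explanation was tested.

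The second pattern is the fall of coding sequences 2733 to 2740 with lysate in deplete cells from T1 to T4. Library-number structure as the whole source is argued against by the smallest of the 4 falls, -3.34 on the log2 scale with blocks of 8 numbers. Without the 8 libraries as well, which were chosen by the level of this run, it was -3.77. The share of counts taken by the tmRNA is argued against by a smallest fall of -3.60 with tmRNA and other non-coding RNA left out. For reads shared with near-identical sequences, the largest percent of non-whole expected counts over the 8 members was 0. A response of the cells to something in the lysate stays open as a hypothesis, and whether iron or another part of the lysate could be responsible was not tested by this design.

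The third pattern is the iron difference in the 4 contrasts, where iron condition and library number run together. The 3 deplete libraries numbered among the replete ones, deplete_NOADD_Tend C and D and deplete_AQUIL_T4 D, were scored again with iron genes taken from AQUIL T0 alone (36 higher, 133 lower), a contrast that uses none of the 3. On this second score they lay at 2.73 to 3.61, within the 2.45 to 3.94 of the other deplete libraries and above the -0.28 to 1.3 of the replete ones. Both ranges leave out deplete_AQUIL_T2 B and replete_L_T3 D. Library-number structure as the whole source is argued against for these iron genes as a set, since 3 of 3 deplete libraries lay with their iron condition and not with their number. The 1 replete library numbered among the deplete ones, replete_L_T3 D, went the other way, with 3.93 on the first iron-gene score. It is among the 8 libraries of the first pattern, whose labels may have been exchanged. The tmRNA was higher in these 3 than in the rest of their groups. It stood at 452101 and 475495 CPM against 89377 to 139820 CPM in the other deplete_NOADD_Tend libraries. In deplete_AQUIL_T4 it stood at 163740 CPM against 75334 to 118633 CPM in the others. It did not match their neighbours by number either. Numbers 15 and 16 lay above their replete neighbours 14 (213876 CPM) and 17 (202945 CPM). Number 54 lay below 53 (312789 CPM) and 55 (350126 CPM). The iron difference of the tmRNA is left open. A difference in depth is argued against by the lowest count of the 4 contrasts, 507, after every library was thinned to 1808192 counts. The smaller counts of 350 and 139 with blocks of 8 numbers leave open how many single genes follow number. An effect of iron supply may remain as a hypothesis, since the cultures' other conditions were not tested.

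Lysate effects differed between iron conditions, by the interaction test of edgeR, in 3 genes at T1, 3 at T2, 20 at T3 and 12 at T4. Changes over time differed between iron conditions in 5 genes in AQUIL and 73 in NOADD. Residuals were drawn in 100 orders, the real one included, in limma fits to the log2 CPM of these groups alone. As many calls as the real number came up in 3 at T1 (9 real, 1025 the highest other), 2 at T3 (10 and 17), 3 at T4 (10 and 538) and 1 in NOADD over time (85 and 3). In NOADD only the real order gave as many, which argues against chance there at the smallest share that 100 orders can give. At T1, T3 and T4 other draws gave as many or more, and the shares were not adjusted over the tests. These counts do not exclude chance at those times. At T0, T2 and in AQUIL over time limma called 0 genes in these fits. Any draw gives at least 0, so the 100 of 100 draws with as many say nothing about chance there, and the highest others were 308, 401 and 20. In the same groups alone edgeR called 0 for lysate by iron interaction T0 (176 at an unadjusted p under 0.05), 0 for lysate by iron interaction T2 (311) and 8 for time by iron interaction AQUIL (271). With all groups the unadjusted count for lysate by iron interaction T0 was 183, with 3 calls by DESeq2 and 540 by limma voom. Draws that call many times the real count, as at T1, T2 and T4, point to a structure of the samples.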

How the results depend on the processing

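The iron contrasts NOADD Tend and AQUIL T4 had at least 1075 calls under each alternative at full depth given here, and 853 and 1077 after thinning every library to 1808192 counts, while coding sequences 2733 to 2740 stayed lower with lysate in deplete cells at T1 to T4 in all of these. Counts of lysate, interaction and time calls moved with single libraries, with library number and with the tool. Where a count moved by over 1.5 times, a list crossed its threshold or the median of a list past its threshold turned, the value is given here, and the cause was not tested except where fewer libraries or a block say so. Settings that use library numbers, leave out libraries named as doubtful or leave out the tmRNA were chosen after seeing the data. Lists of genes by function and fry on them were not run, since the files do not pair identifiers with products. Depth limits the counts: libraries held 1808191 to 16843103 counts without rRNA and tRNA. After thinning, iron counts were 527 in NOADD Tm1 and 507 in AQUIL T0. For lysate they were 21 at T2 and 21 at T4 in deplete cells, and 1, 5 and 1 at T0 to T2 in replete cells. For time they were 145 in deplete NOADD, 1 in replete AQUIL and 0 by edgeR in replete NOADD. The interaction had 1 at T0 and 0 by edgeR at T2, and time by iron 10 in AQUIL and 18 in NOADD. In what follows, list medians are log2 lysate effects of the 26 genes higher or the 76 genes lower under iron depletion, and time by iron is the change over time compared between iron conditions.

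Leaving out each library in turn gave ranges of 22 to 49 for lysate in deplete cells at T2 and 24 to 121 at T4. In replete cells they were 0 to 8 at T0, 5 to 8 at T1, 0 to 8 at T2, 0 to 1 at T3 and 0 to 1 at T4. The interaction ranged from 0 to 5 at T0, 0 to 19 at T2, 12 to 27 at T3 and 10 to 35 at T4. Changes over time ranged from 28 to 86 in deplete AQUIL, 197 to 380 in deplete NOADD and 0 to 6 in replete NOADD, and time by iron from 0 to 22 in AQUIL and 34 to 1.1e+02 (73 higher, 40 lower) in NOADD. In deplete cells medians of the 26 genes ranged from -0.18 to 0.14 at T0 and from -0.019 to 0.21 at T2, and those of the 76 genes from -0.0056 to 0.094 at T0, -0.021 to 0.095 at T1, -0.41 to 0.13 at T2 and 0.084 to 0.30 at T4. For replete cells the 26 genes ranged from -0.15 to 0.041 at T0, 0.045 to 0.12 at T1, -0.10 to 0.059 at T2, -0.061 to 0.45 at T3 and -0.13 to 0.047 at T4, and the 76 genes from 0.053 to 0.21 at T2.

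With DESeq2 size factors, time in replete NOADD had 0 calls by edgeR and time by iron in AQUIL 13, and the 76 genes lost 2 calls: iron-depletion-low genes under lysate deplete T0 (0.044, adjusted p = 0.0688) and iron-depletion-low genes under lysate deplete T4 (0.22, adjusted p = 0.0588). With no count filter the counts were 37 for lysate in deplete cells at T3, 0 for time in replete NOADD and 10 for time by iron in AQUIL. A mean of 50 counts, and leaving out tmRNA and other non-coding RNA, each gave 0 for time in replete NOADD. With rRNA and tRNA kept, time in replete NOADD had 0 calls and time by iron in AQUIL 13. The main count for time in replete NOADD was 1 by edgeR, with 306 genes at an unadjusted p under 0.05, 12 calls by DESeq2 and 1077 by limma voom.

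With the replicate block, lysate in replete cells at T3 and time in replete NOADD had 0 calls and time by iron in AQUIL 8. With the replicate block within each iron condition these were 0, 0 and 14. Pairs of same letters correlated above 0.1 throughout in 1 of 18 contrasts only, time in replete AQUIL (0.334 to 0.745), where edgeR called 0 genes with and without the block. The letter within iron condition also ended the call of AWH74560.1 in the interaction at T3 (4.01, adjusted p = 0.101), and neither block moved another count by over 1.5 times or ended another call.

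With blocks of 8 library numbers the iron counts were 350 in NOADD Tm1 and 139 in AQUIL T0. Lysate counts in deplete cells were 9 at T0, 66 at T2, 1.1e+02 (51 higher, 63 lower) at T3 and 128 at T4, and in replete cells 4 at T2 and 0 at T3. Time counts were 379 in deplete AQUIL, 627 in deplete NOADD and 14 in replete NOADD. The interaction had 6 at T0, 7 at T2, 12 at T3 and 36 at T4, and time by iron 40 in AQUIL and 302 in NOADD. In deplete cells the 26 genes had medians of -0.078 at T1 and 0.064 at T2, and the 76 genes turned to -0.14 at T1 and 0.0039 at T2. In replete cells the 76 genes turned to -0.012 at T2, and the 26 genes, past no threshold, to 0.022 at T0, -0.0063 at T1 and 0.0096 at T4.

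Without the 2 libraries deplete_AQUIL_T2 B and replete_L_T3 D, lysate counts in deplete cells were 60 at T1, 57 at T2, 62 at T3 and 91 at T4, and in replete cells 6 at T0 and 0 at T3. Time counts were 1.1e+02 (75 higher, 40 lower) in deplete AQUIL and 10 in replete NOADD, interaction counts 5 at T1, 21 at T2, 12 at T3 and 21 at T4, and time by iron in AQUIL 31. In deplete cells the 26 genes stood at -0.019 at T2, and the 76 genes at 0.13 at T2 (turned) and 0.23 at T4. For replete cells the 26 genes turned to -0.061 at T3.

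Without the 8 libraries that stand apart, lysate counts were 11, 61, 60 and 66 in deplete cells at T0 to T3, and 14, 8 and 9 in replete cells at T0, T3 and T4. Time counts were 129 in deplete AQUIL and 13 in replete NOADD, interaction counts 10 at T1, 18 at T2 and 10 at T3, and time by iron in AQUIL 23. In deplete cells the 26 genes stood at -0.019 at T2 and the 76 genes at 0.13 at T2 (turned) and 0.23 at T4. In replete cells the 26 genes turned to -0.021 at T3 and, past no threshold, to 0.060 at T2.

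With blocks of 8 library numbers and without the 8 libraries together, lysate counts in deplete cells were 39 at T0, 151 at T2, 198 at T3 and 126 at T4, and in replete cells 14 at T0, 8 at T3 and 9 at T4. Time counts were 469 in deplete AQUIL, 705 in deplete NOADD and 17 in replete NOADD. The interaction had 6, 18, 21, 12 and 20 at T0 to T4, and time by iron 39 in AQUIL and 304 in NOADD. In deplete cells the 26 genes stood at -0.080 at T2, and the 76 genes at 0.20 at T2 (turned) and 0.19 at T4. For replete cells the 76 genes turned to -0.039 at T0 and stood at 0.039 at T2 and -0.022 at T3, and the 26 genes stood at 0.029 at T3 and, past no threshold, turned to -0.069 at T1, 0.043 at T2 and 0.11 at T4.

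With the list by adjusted p alone, 318 and 321 genes, the median was -0.023 for iron-depletion-high genes under lysate deplete T0, and for the same list -0.099, 0.093 and -0.049 in replete cells at T0 to T2. The lower list had 0.013 at T0 in deplete cells, and iron-depletion-low genes under lysate deplete T1 turned to -0.0035. With the list from AQUIL T0, 36 and 133 genes, iron-depletion-high genes under lysate deplete T0 stood at -0.098, T1 at -0.22 and iron-depletion-high genes under lysate deplete T2 at 0.0065. The lower genes had 0.022 at T1, 0.014 at T3 and 0.17 at T4 in deplete cells and 0.10 in replete cells at T0. With an estimated correlation the medians stay as they are by construction and no list passed. Those whose call ended were the 26 genes in deplete cells (-0.031, -0.51, -0.24 and -0.082 at T0, T1, T3 and T4) and in replete cells at T3 (0.30). They were also the 76 genes in deplete cells (0.038, 0.037, -0.28, 0.19 and 0.21 at T0 to T4) and in replete cells (0.20, -0.19, 0.12, -0.35 and -0.14). The adjusted p ran from 0.126 to 0.631 for these.

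With the DESeq2 Wald test the counts were 59 for lysate in deplete cells at T3, 1.1e+02 (76 higher, 31 lower) for time in deplete AQUIL and 12 in replete NOADD. The interaction had 3 at T0, 5 at T1, 8 at T2 and 21 at T4, and time by iron 23 in AQUIL and 1.2e+02 (89 higher, 27 lower) in NOADD. With limma voom and quality weights the counts were 1395 for iron effect NOADD Tm1, 2044 for iron effect NOADD Tend and 1844 for iron effect AQUIL T0. They were 281 for lysate effect deplete T0, 280 for lysate effect deplete T1, 224 at T2, 293 for lysate effect deplete T3 and 124 at T4. They were 614 for lysate effect replete T0, 1301 for lysate effect replete T1, then 13, 19 and 16. Over time they were 279 for time effect deplete AQUIL, 951 for time effect deplete NOADD and 1077 in replete NOADD. The limma voom interaction counts were 540 for lysate by iron interaction T0, 1073 for lysate by iron interaction T1, then 51, 35 and 44, with 46 for AQUIL and 545 for time by iron interaction NOADD. In fits of only the groups of the contrast, with fewer libraries behind the spread, lysate had 15 at T2 and 16 at T4 in deplete cells, and 4 at T2 and 0 at T3 in replete cells. Time had 202 in deplete AQUIL, 744 in deplete NOADD and 0 in replete NOADD, the interaction 9 at T1, 0 at T2 and 10 at T3, and time by iron in AQUIL 8.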

Other observations

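All tests in this part other than the counts of splits were chosen only after the results were seen.

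Most genes called over time in deplete AQUIL were also called in deplete NOADD, while most of those called in NOADD were not called in AQUIL. Of 43 genes that rose from T0 to T4 in AQUIL, 37 were among the 162 that rose from Tm1 to Tend in NOADD, where 2.24 would be expected of independent lists, and of 22 that fell, 15 were among 231 (1.63 expected). Across 3108 genes without the run of 8 neighbours, the log2 changes over time of these media correlated at r = 0.722, and genes are not independent replicates. Of the 162 genes that rose over time in NOADD, 91 were also higher in deplete than in replete cells at Tend, and of the 231 that fell, 93 were also lower. At Tm1 more lay the other way: 26 of the 162 were higher and 38 lower in deplete cells, and of the 231, 20 were lower and 37 higher. These contrasts share the deplete_NOADD_Tend or deplete_NOADD_Tm1 libraries with the change over time, so part of each overlap comes from shared values.

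Many genes called lower with lysate in deplete cells at T1 to T4 were higher under iron depletion in other libraries, with the fewest of these times at T2. Of 28 genes lower with lysate at T4, 24 were higher in deplete than in replete cells in NOADD Tend, where 5.29 would be expected of independent lists (Fisher's exact test, adjusted p = 1.01e-13 over 40 overlaps), and 1 was lower. Of 32 genes higher with lysate at T4, 15 were lower in deplete cells in NOADD Tend (7.49 expected, adjusted p = 0.00942) and 0 of the edgeR calls were higher (6.05 expected). At T1, 9 of 9 genes higher with lysate were lower in deplete cells (2.11 expected, adjusted p = 4.76e-06), and 18 of 29 lower ones were higher (5.48 expected, adjusted p = 9.22e-07). At T2, 14 of 28 lower ones were higher in deplete cells (adjusted p = 0.000415) and 7 were lower (6.55 expected), and the 4 genes higher with lysate lay in neither list of edgeR calls. Of the 76 genes lower under iron depletion 4 were called lower there. Their median of -0.28 became 0.13 without deplete_AQUIL_T2 B, 98 of 100 splits gave one as large, and camera gave an adjusted p = 0.542 with an estimated correlation. At T3, 16 of 18 lower ones were higher (3.40 expected, adjusted p = 7.82e-10) and 1 was lower, and 5 of 6 higher ones were lower (1.4 expected, adjusted p = 0.00671). The 8 neighbours 2733 to 2740 are among the lower genes at each of T1 to T4, and all were higher in deplete cells in NOADD Tend. At T2 they make up 8 of the 14 shared genes. Fisher's test treats genes as independent.

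A hypothesis drawn from these overlaps is that lysate opposes the change over time in deplete cells. Across the 3108 genes without the run, the lysate effect in deplete cells and the change over time in NOADD, which share no libraries, correlated at -0.13, -0.32, -0.47 and -0.23 at T1 to T4. With lysate effects taken from means of log2 levels these were -0.14, -0.31, -0.50 and -0.29. By exact permutation of the 10 libraries on these means (252 arrangements, one-sided), p = 0.286, 0.151, 0.0357 and 0.175, and the smallest adjusted p was 0.143. With blocks of 8 numbers and without the 8 libraries the correlations were -0.32, -0.34, -0.43 and -0.29. Chance was not excluded, and the direction may still be real.

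The counts of calls were set against 100 of the 126 splits of the 10 libraries of each contrast, in fits of those libraries alone by edgeR. For iron, 1 split gave as many genes in each contrast, the real one: 956 in NOADD Tm1, 1233 against 330 for the highest other in NOADD Tend, 675 against 198 in AQUIL T0 and 1540 against 304 in AQUIL T4. A share of 1 in 100 is the smallest these splits can give, and it argues against chance for these counts. The real splits parted the library numbers by 1, 0.726, 1 and 0.968 of the widest possible gap. In NOADD Tm1, AQUIL T0 and AQUIL T4 the splits therefore cannot tell iron from library number. In NOADD Tend the highest other split parted the numbers more than the real one, by 0.904. For lysate in deplete cells 2, 1, 2, 3 and 2 splits gave as many at T0 to T4. The real counts were 3, 54, 15, 29 and 16 and the highest others 9, 3, 154, 347 and 70. At T1 only the real split gave as many, which argues against chance there at the smallest share of 1 in 100. At T0, T2, T3 and T4 other splits gave as many or more, and the shares were not adjusted over the contrasts. These counts do not exclude chance there. For lysate in replete cells 3 splits gave as many at T1 (7 real, 1751 the highest other) and 2 at T2 (4 and 1279). These shares were not adjusted either, so the counts do not exclude chance. At T0, T3 and T4 edgeR called 0 genes, so the 100 of 100 splits with as many say nothing about chance, and the highest others were 590, 1290 and 917. With all groups the unadjusted counts there were 306, 93 and 44, DESeq2 called 0, 1 and 0, and limma voom 614 for lysate effect replete T0, then 19 and 16. For the change over time only the real split gave as many in deplete AQUIL and in deplete NOADD. Real and highest other counts were 202 and 146 in AQUIL and 744 and 25 in NOADD. This argues against chance at the smallest share of 1 in 100, without adjustment. In AQUIL the highest other count came near the real one. In replete AQUIL and replete NOADD the real count by edgeR was 0 and the highest others 1064 and 590, so the splits say nothing about chance there either. The unadjusted counts with all groups were 71 and 306, DESeq2 called 0 and 12 genes, and limma voom 0 and 1077. Splits that call many times the real count in replete cells, and at T2 and T3 in deplete cells, point to a structure of the samples. The highest split at T3 in deplete cells parted the library numbers by 0.894 of the widest possible gap against 0.404 for the real split. At T2 there it was 0.673 against 0.184. For lysate in replete cells at T0 to T3 the highest splits had 0.48, 0.617, 0.714 and 0.716 against 0.32, 0.348, 0.267 and 0.227. Over time in replete cells they had 0.136 against 0.0847 in AQUIL and 0.953 against 0.531 in NOADD. At T4 the highest split parted them less than the real one, both in deplete cells (0.205 against 0.410) and in replete cells (0.108 against 0.197). This gap compares mean numbers only and misses a structure in which middle numbers stand apart, so number stays open for these counts. With blocks of 8 numbers in the fit, 51 genes were higher and 63 lower at T3 in deplete cells.

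Medians of the iron lists were compared with the same splits by size. In deplete cells at T0 to T4, 92, 1, 78, 6 and 37 of 100 splits gave a median as large for the 26 genes, with real values of -0.02, -0.50, 0.12, -0.25 and -0.08 and highest others of 0.47, 0.35, 0.44, 0.32 and 0.24 in size. At T1 alone no other split gave a median as large, at the smallest share of 1 in 100. This is 1 of 20 list tests and was not adjusted, so chance is not excluded there. At T1 the median was -0.078 with blocks of 8 numbers, and camera gave an adjusted p = 0.542 with an estimated correlation. For the 76 genes 57, 46, 98, 19 and 9 splits did, with real values of 0.04, 0.07, -0.30, 0.21 and 0.24 and highest others of 0.17, 0.21, 0.56, 0.31 and 0.30. In replete cells 83, 37, 82, 86 and 88 splits did for the 26 genes (real -0.03, 0.07, -0.05, 0.32 and -0.01, highest others 0.29, 0.30, 0.30, 0.60 and 0.19). For the 76 genes there 21, 29, 47, 22 and 31 did (real 0.19, -0.20, 0.11, -0.34 and -0.14, highest others 0.43, 0.50, 0.47, 0.58 and 0.32). Chance cannot be excluded for the 26 or the 76 genes at any time in either iron condition.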
